A study of Mus musculus with 32 samples.

How the data were processed

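Liver RNA from 32 mice was measured by bulk sequencing of polyadenylated RNA. The labels cross a knockout of the thyroid hormone receptor beta gene (Thrb) with thyroid hormone and with carbon tetrachloride (CCl4), which gives 8 groups of 4 animals. Each library carries an animal number of its own in the labels, so the replicates are separate animals and the spread between them is biological as well as technical. Per the labels' protocols, the mice were fed a PTU/LID diet, which blocks thyroid hormone synthesis and makes mice hypothyroid. CCl4, a solvent that liver cytochrome P450 enzymes turn into a toxic radical, was injected at 0.4 µl/g for 4 weeks, 2 times a week, 9 injections in all. Triiodothyronine (T3), the active thyroid hormone, was given at 1 µg/ml in the drinking water in the last week, and RNA was taken 24 hours after the last injection. Control animals received phosphate-buffered saline (PBS) in place of T3 or oil in place of CCl4, as the labels name them.

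The authors deposited 1 table of raw counts per gene for all libraries, in whole numbers that are not normalized. Per the submitters' processing notes, FastQC 0.11.5, Trim Galore, cutadapt and STAR 2.7.9a were used with the genome build GRCm38, with no role or order stated. The counting tool, its strand setting and the annotation release are not given in the sources used here. The labels' protocols name 2 library kits, TruSeq v2 and TruSeq Stranded, without saying which library was made with which, so a kit batch cannot be separated from the groups. Without a known strand setting, reads of a gene and of its antisense partner cannot be told apart, and near-identical paralogs (the Mup, Cyp2b, Cyp2c, Cyp3a, Saa, haemoglobin and Sult families) can exchange reads, so their values are uncertain.

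The table lists 52636 genes by Ensembl identifier. GENCODE vM21, an annotation of GRCm38, gave a symbol and position for 52403 of them, and the 233 without a match held at most 0.0656% of the counts of any library. Positions are given 1-based on GRCm38. All genes entered the library totals. Of the sex-linked genes, the Y-linked ones held 3 counts over all libraries together, so all libraries came from females.

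Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on the raw counts, with TMM factors, the filterByExpr filter by group (a minimum count of 10, a minimum total of 15) and the quasi-likelihood F test. The filter kept 15599 genes, which held at least 99.5% of the counts of each library. All 32 libraries entered 1 fit with a mean for each group, so that the 16 comparisons share 1 estimate of the spread. The 16 are 12 differences between groups that differ in 1 factor and 4 interactions. Interactions are coded as knockout minus wild type, or as CCl4 minus oil. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p of 0.05 with no minimum fold. Adjusted p-values beside single genes come from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Fold changes are log2 values from the fit and each is printed with its standard error (SE). Levels are CPM (a count scaled to a common library total), computed here from the counts with the TMM factors and given as mean ± SD over 4 animals.

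The tests, lists and the rule for named genes were fixed before the data were examined. The rule names Thrb and the second receptor gene Thra. From each list described it names up to 4 called members with the smallest adjusted p and up to 3 called against the majority. For the 5 main comparisons it adds the 6 largest rises and 6 largest falls among called genes that reach 5 CPM in a group and, for 2 groups, do not overlap between them, with clone names left out. Some genes that the rule names are not reported here. The 5 are CCl4 in wild-type PBS animals, T3 in wild-type animals on oil, T3 in wild-type animals on CCl4, the difference between genotypes in the T3 response on CCl4, and the genotypes compared on T3 and CCl4. For other comparisons it names the 4 smallest adjusted p, and a count of 5 or fewer names all its genes.

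The 25 lists cover matrix genes, myofibroblasts, quiescent stellate cells, TGF-β targets, matrix-degrading enzymes, Kupffer cells, monocyte-derived macrophages, neutrophils, lymphocytes, cholangiocytes, sinusoidal endothelium, cell cycle, T3 targets, pericentral and periportal hepatocyte genes, xenobiotic cytochrome P450 enzymes, bile acid handling, cholesterol synthesis, lipogenesis, fatty acid oxidation, oxidative phosphorylation, acute-phase proteins, stress genes, proteins secreted by hepatocytes, and blood or other tissues. Each was compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, then again with the correlation estimated from the data. The fry test, which uses no other genes, was also run and is given only where named. In brackets, a count followed by "alone" is adjusted over the list alone and, where absent, was the same. The lists came from general knowledge of liver, not from these libraries, and share some genes.

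The share of injury genes moved back by T3 was read without shared libraries. For wild type, genes were chosen by the CCl4 comparison in knockout PBS animals and read in the T3 comparison of wild-type CCl4 animals, and for knockout the other way round. Overlaps are set beside the number that independent lists of the same sizes would share.

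Total counts per library ran from 16985162 to 26118055. A floor of 3 counts, the most that a count of 0 allows at 95% confidence, came to between 0.115 and 0.177 CPM per library. Where a group held no counts of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only. Simulated counts for T3 on CCl4 in wild type, with 200 of 15599 genes changed, tested the procedure. It found 29.9%, 73.1% and 95.5% of genes changed 1.5-, 2- and 4-fold, and 4.76% of its calls were unchanged genes. The real comparison called 6506, so the rates may not apply.

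Alternatives were DESeq2 1.42.0, relative log expression in place of TMM, no filter on low counts, only the groups compared in the fit, the replicate number as a block, and each library left out in turn. Scaling by total counts alone and leaving out the 2 libraries farthest from their groups were added after the data were seen. Other splits of the libraries were counted for each comparison. No library was left out of the results reported.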

Results

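Gene expression was measured in the livers of 32 female mice by sequencing polyadenylated RNA, 1 library per mouse. Wild-type mice and mice with a knockout of Thrb, which encodes thyroid hormone receptor beta, were made hypothyroid by diet. They were injected with CCl4, which damages hepatocytes and causes fibrosis, or with oil, and were given T3 or PBS in the last week. The 8 combinations of genotype, hormone and injection had 4 mice each. The title of the series names receptor action in the resolution of liver fibrosis, so the comparisons asked what CCl4 changed, what T3 changed in uninjured and injured livers, and whether the genotypes differed. The first 2 principal components held 32.7% and 25.7% of the variance. By distance in log2 CPM over all tested genes, the libraries farthest from the mean of their groups were wild-type PBS CCl4 replicate 2 (113.75) and knockout PBS CCl4 replicate 3 (103.81).

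Thrb (ENSMUSG00000021779, chromosome 14, 17660261 to 18038090) kept reads in all knockout livers. In wild type it measured 59.1 ± 7.10 CPM on PBS and oil, 23.5 ± 9.38 on PBS and CCl4, 48.1 ± 8.40 on T3 and oil and 40.5 ± 5.35 on T3 and CCl4 (mean ± SD, n = 4 mice here and below). In knockouts the same groups measured 35.9 ± 4.94, 20 ± 3.18, 29.5 ± 4.95 and 20.2 ± 3.47 CPM. By library, from replicate 1 to 4, wild-type PBS oil livers held 56.9, 62.8, 66.4 and 50.2 CPM of Thrb, wild-type PBS CCl4 livers 23.8, 10.7, 33.2 and 26.3, wild-type T3 oil livers 44.1, 44.3, 60.6 and 43.2, and wild-type T3 CCl4 livers 43.9, 40.98, 44.4 and 32.8. Knockout PBS oil livers held 30.7, 35.7, 42.6 and 34.7 CPM, knockout PBS CCl4 livers 23.1, 21.9, 15.9 and 19.1, knockout T3 oil livers 33.7, 22.7, 32.5 and 29.03, and knockout T3 CCl4 livers 24.4, 19.99, 15.9 and 20.3. The knockout effect on Thrb was called on T3 and CCl4 (log2 fold change -1.01 ± 0.21 SE, adjusted p = 9.66e-04) and on T3 and oil (-0.70 ± 0.21, adjusted p = 0.0207), the latter not without knockout T3 oil replicate 2 or wild-type T3 oil replicate 3. It was not called on PBS and oil (adjusted p = 0.167) or on PBS and CCl4 (adjusted p = 0.600). Counts per gene do not show which exon was removed, so they do not fully check the deletion. Thra (ENSMUSG00000058756, chromosome 11, 98740638 to 98769006), which encodes the other nuclear T3 receptor, was at 8.38 ± 1.79 CPM in knockouts and 12.7 ± 2.31 in wild type on T3 and CCl4.

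Dio1 (ENSMUSG00000034785, chromosome 4, 107291465 to 107307169), a T3-induced gene for a hormone deiodinase, separated genotype and hormone without overlap. All 8 wild-type PBS livers held at most 1.00 CPM, all 8 knockout PBS livers 3.95 to 20.03, all 8 knockout T3 livers 77.4 to 135, and all 8 wild-type T3 livers at least 845 CPM.

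**Figure D1:**
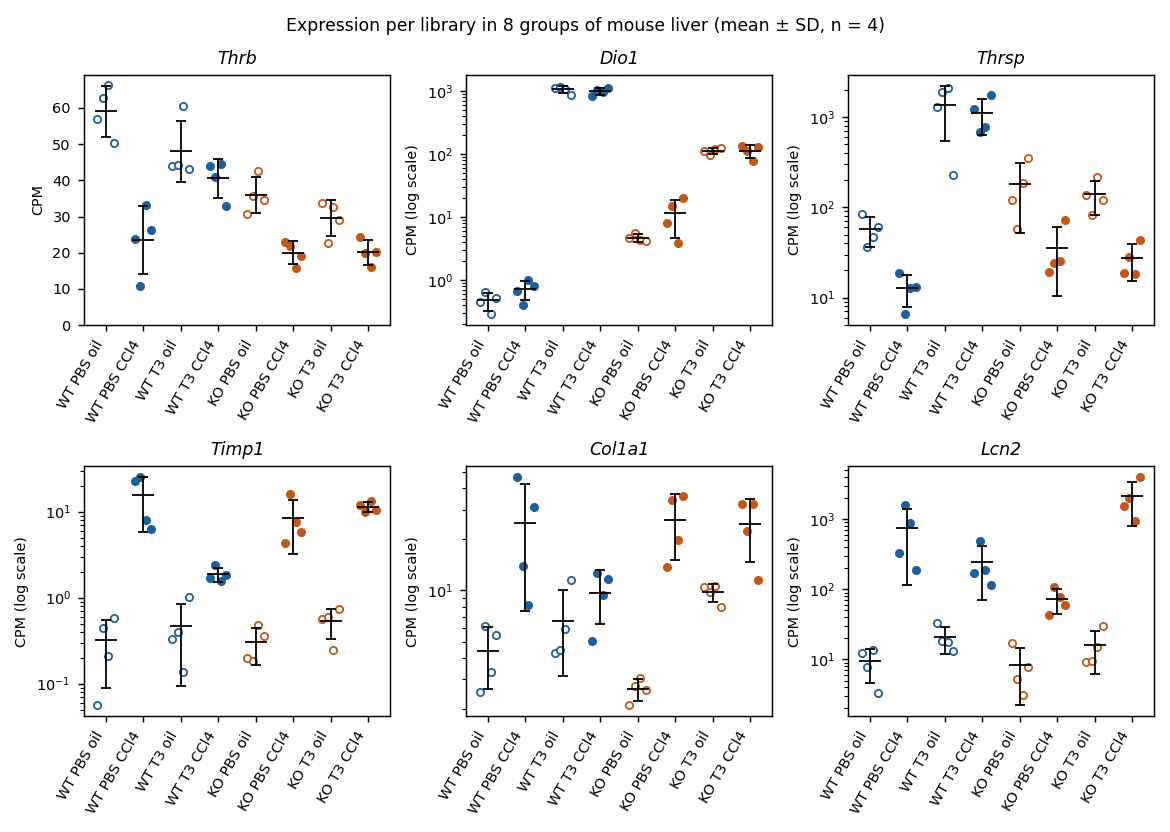
Levels of Thrb, Dio1, Thrsp, Timp1, Col1a1 and Lcn2 in CPM (log axes except Thrb) for each of the 32 libraries by group, with open points for oil, filled points for CCl4, blue for wild type, orange for knockout, and bars for mean ± SD. Dio1 was at least 845 CPM in the wild-type T3 livers and at most 1.00 CPM in the wild-type PBS livers.

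CCl4 in wild-type PBS mice measured the injury. Many fibrosis, myeloid cell and acute-phase genes rose, though none of their lists held with an estimated correlation. Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), which blocks matrix breakdown, rose from 0.320 ± 0.232 to 15.5 ± 9.70 CPM (log2 fold change 5.58 ± 0.56, adjusted p = 6.36e-08). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), the main fibrillar collagen gene of scars, rose from 4.38 ± 1.75 to 24.95 ± 17.4 CPM (2.51 ± 0.45, adjusted p = 7.54e-05). Loxl2, a collagen cross-linking enzyme, rose by 1.85 ± 0.26 and Tagln, a contractile gene of myofibroblasts, by 1.67 ± 0.36. Cd14, a myeloid receptor for bacterial lipid, rose by 6.16 ± 0.59, Mmp12, a macrophage elastase, by 5.66 ± 0.63, and Hmox1, which degrades haem under oxidative stress, by 2.13 ± 0.22. Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), a secreted iron-trapping protein of the acute phase, rose from 9.35 ± 4.74 to 751 ± 637 CPM. Sprr1a, a gene of stressed epithelia, and Slc7a11, which imports cystine, had some of the largest rises (11.32 ± 1.37 and 7.97 ± 0.74). Fosl1, a transcription factor of the AP-1 family, had 1 count in the oil group and a ratio of 1732 (95% counting interval 310.6 to 68441).

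Of 25 matrix genes 17 were called higher and 1 lower in this comparison (17 and 2 when adjusted over the list alone), with a list adjusted p of 3.02e-04, and 0.358 with an estimated correlation. The member called lower was Col14a1, a fibril-associated collagen, and that call was lost without wild-type PBS CCl4 replicate 3 or wild-type PBS oil replicate 4. The lists for myofibroblasts (9 of 17 higher, 1 lower), TGF-β targets (9 of 14, 11 alone), matrix-degrading enzymes (15 of 20 higher and 1 lower, 16 and 1 alone), monocyte-derived macrophages (16 of 17), neutrophils (10 of 10), cholangiocytes (6 of 12), acute-phase proteins (11 of 18) and stress genes (13 of 15 higher and 1 lower) were called higher. So was the cell cycle list (12 of 22, 13 alone). Cholangiocyte genes lost their list call when libraries were scaled by total counts alone (adjusted p = 0.0701). Quiescent stellate cell genes were called lower (4 of 13, adjusted p = 0.0302), but not without wild-type PBS CCl4 replicate 3 (0.113) or wild-type PBS oil replicate 4 (0.0501). Kupffer cell, lymphocyte, sinusoidal endothelium and blood genes were not called as lists (adjusted p of 0.260, 0.352, 0.0943 and 0.900). For the blood list the median was 0.50 and the mean 0.06, while the test pointed down.

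Many hepatocyte genes fell after CCl4 in wild-type PBS mice, again with no list that held with an estimated correlation. Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774987), the pericentral enzyme that activates CCl4, fell from 7644 ± 3130.0 to 1063 ± 587 CPM (-2.85 ± 0.45, adjusted p = 2.01e-05). Slc1a2, a pericentral glutamate transporter, and Cps1, the entry enzyme of the periportal urea cycle, fell too (-5.44 ± 0.71 and -1.47 ± 0.25). Alb, the gene for serum albumin, fell from 115000 ± 18700.0 to 44210 ± 6990.0 CPM. Esrrg, a nuclear receptor of energy metabolism, also fell (-4.50 ± 0.43). Thrb itself fell (-1.33 ± 0.21, adjusted p = 2.32e-05), and so did Thra (-1.27 ± 0.21, adjusted p = 3.39e-05). The lists for pericentral (8 of 15 lower, 9 alone) and periportal hepatocytes (11 of 14), cytochrome P450 enzymes (12 of 19 lower and 1 higher, 13 and 1 alone), bile acid handling (11 of 14, 12 alone), lipogenesis (13 of 15), fatty acid oxidation (13 of 18, 16 alone), oxidative phosphorylation (14 of 18 lower and 1 higher), secreted proteins (9 of 12) and cholesterol synthesis (9 of 20) were called lower. The cholesterol list was not called without wild-type PBS CCl4 replicate 4 (adjusted p = 0.0560). The member of oxidative phosphorylation that rose was Cycs, the electron carrier that also triggers apoptosis (0.54 ± 0.11). T3 targets were not called (adjusted p = 0.384). The 20 lists called in this comparison ran from 0.0655 to 0.475 with an estimated correlation.

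Of 15599 genes tested, 7201 were called after CCl4 in wild-type PBS mice, 3834 higher and 3367 lower. Scaled by total counts alone, 6949 were higher and 1545 lower, so the split between rises and falls depends on the scaling. With only the compared groups in the fit the count was 4590.

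In knockout PBS mice CCl4 also raised many fibrosis and myeloid genes. Col1a1 rose by 3.31 ± 0.47 (adjusted p = 1.38e-05), Timp1 by 4.72 ± 0.56 (adjusted p = 1.18e-06) and Gpnmb, a gene of lipid-laden macrophages, by 5.36 ± 0.61. Tagln2, an actin-binding protein gene, S100a11, a calcium-binding protein gene, Cd63, a lysosome membrane gene, and Wfdc3, a protease inhibitor gene, had the smallest adjusted p, with changes of 1.78 ± 0.16, 2.96 ± 0.28, 4.17 ± 0.41 and 6.33 ± 0.62. Matrix genes (18 of 25 higher, 21 alone, list adjusted p = 6.76e-10), myofibroblast genes (10 of 17, 14 alone) and cell cycle genes (19 of 22) were called higher, without holding with an estimated correlation (adjusted p of 0.200, 0.0884 and 0.0884). Monocyte-derived macrophages (13 of 17, 16 alone), matrix-degrading enzymes (12 of 20) and stress genes (13 of 15) held, at 0.0139, 0.0444 and 0.0359. Also called, but not with an estimated correlation (0.0884 to 0.521), were TGF-β target, neutrophil, Kupffer cell and cholangiocyte genes, higher, and quiescent stellate, sinusoidal endothelium, pericentral, periportal, P450, bile acid, lipogenesis, fatty acid oxidation, oxidative phosphorylation and secreted protein genes, lower. Of these the Kupffer cell, stellate, endothelium, fatty acid oxidation and secreted protein calls ended without single libraries (0.0504 to 0.151). Acute-phase genes were not called as a list. In all, 4854 genes were called, 2770 higher and 2084 lower. Scaled by total counts alone these were 5485 and 865, and without knockout PBS CCl4 replicate 3 the count was 2987.

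The difference between genotypes in the CCl4 response on PBS was called for 3 genes, all smaller in knockouts, against 4 with DESeq2, and 1242 genes had an unadjusted p below 0.05. They were Saa1 and Saa2, acute-phase serum proteins that can exchange reads (-5.81 ± 1.06 and -7.23 ± 1.32), and Ciapin1, an iron-sulfur assembly factor (-0.98 ± 0.18), each at an adjusted p of 0.0383. Left out in turn, single libraries moved the count between 0 and 14. The acute-phase list was called lower (2 of 18, 10 alone, list adjusted p = 2.19e-14), and the adjusted p was 0.171 with an estimated correlation. Matrix and myofibroblast genes were called with a larger CCl4 response in knockouts (medians 0.32 and 0.47, adjusted p of 0.0130 for both, 0.908 and 0.821 with an estimated correlation), with no member called (1 alone for myofibroblasts). The matrix call ended without any 1 of 5 libraries, at most 0.626 without wild-type PBS CCl4 replicate 3, and the myofibroblast call without any 1 of 3, at most 0.199 without the same library. Cell cycle, periportal, bile acid, cholesterol, fatty acid oxidation, oxidative phosphorylation and secreted protein genes were called higher and neutrophils lower, with no called member and 0.821 to 0.913 with an estimated correlation. Of these only cell cycle and fatty acid oxidation stayed called whichever library was left out. Genes called in both genotypes went the same way in all cases, with 2168 higher and 1697 lower in both where 680.8 and 449.8 would be shared by independent lists.

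T3 in uninjured wild-type mice gave the hormone response without CCl4. Hormone targets, Kupffer cell genes and cell cycle genes rose, and 12 of 19 drug-metabolizing genes of the cytochrome P450 list fell, with 1 higher. The Kupffer cell (0.0579) and P450 lists (0.349) did not hold with an estimated correlation. Dio1 rose from 0.482 ± 0.152 to 1068 ± 146 CPM (11.12 ± 0.45, adjusted p = 1.07e-16), and Thrsp (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730), a lipogenic regulator, from 57.1 ± 20.3 to 1381 ± 841 CPM (4.60 ± 0.61). Gpd2, a mitochondrial enzyme of the glycerol phosphate shuttle, rose by 3.91 ± 0.21. Folr2 and Timd4, surface genes of resident Kupffer cells, rose by 3.10 ± 0.31 and 2.64 ± 0.29. Rrm2, which makes deoxynucleotides, rose by 4.05 ± 0.37, Cdk1, the mitotic kinase, by 4.78 ± 0.45, and Ccnd1, the cyclin of cell cycle entry, by 3.96 ± 0.39. Col12a1, a fibril-associated collagen, rose by 3.01 ± 0.30. Genes that fell included Cyp2e1 (-2.83 ± 0.45) and Cyp2c54, a P450 enzyme that can exchange reads with its paralogs (-9.97 ± 1.01). Mup18, a secreted pheromone carrier of a gene family with near-identical members, had no counts on PBS and rose at least 3302-fold. The P450 gene Cyp3a41a, also of a paralog family, had 2 counts on PBS and a ratio of 3724 (95% counting interval 1031 to 30753). Thra fell (-0.76 ± 0.21, adjusted p = 5.36e-03) and Thrb was not called (adjusted p = 0.282).

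As lists, T3 targets (11 of 15 higher, median 3.02) and cell cycle genes (20 of 22 higher, median 4.20) were called higher in uninjured wild-type mice and held with an estimated correlation (adjusted p of 7.56e-04 and 0.0409). Kupffer cell genes (12 of 12 higher, median 2.36) were called at 2.21e-13 and had an adjusted p of 0.0579 with an estimated correlation. Cytochrome P450 genes (12 of 19 lower, with Cyp3a41a higher), monocyte-derived macrophages (11 of 17), cholesterol synthesis (14 of 20, 16 alone), lipogenesis (8 of 15 higher and 1 lower, 9 and 1 alone), fatty acid oxidation (5 of 18 lower), lymphocytes (5 of 18) and blood and other tissues (6 of 7 higher, Alas2 of haem synthesis lower) were called too and did not hold with an estimated correlation, where they had adjusted p of 0.349, 0.562, 0.846, 0.846, 0.846, 0.846 and 0.562. Calls for lymphocytes, lipogenesis and fatty acid oxidation each ended when single libraries were left out. Lymphocytes were not called without wild-type T3 oil replicate 2 (0.0513) or 4 (0.119), or wild-type PBS oil replicate 3 (0.125) or 4 (0.0566). Lipogenesis was not called without wild-type T3 oil replicate 3 (0.0608), nor fatty acid oxidation without wild-type T3 oil replicate 2 (0.0513) or wild-type PBS oil replicate 2 (0.0539). Matrix (adjusted p = 0.787), myofibroblast (0.229), TGF-β target (0.974) and acute-phase genes (0.420) were not called. For stress genes the median was -0.23 and the mean -0.26, while the test pointed up, and the adjusted p was 0.963. In all, 5501 genes were called, 2970 higher and 2531 lower, and 3427 and 1683 when scaled by total counts alone.

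In uninjured knockout mice T3 raised Kupffer cell and cell cycle genes but not the T3 targets as a list. Timd4 rose by 2.62 ± 0.29 (adjusted p = 2.99e-07), Clec4f, a lectin of Kupffer cells, by 2.57 ± 0.31 and Top2a, a topoisomerase of dividing cells, by 4.74 ± 0.56 (adjusted p = 7.14e-07). Dio1 rose by 4.59 ± 0.33, Ifi27l2a and Xaf1, interferon-induced genes, by 2.97 ± 0.24 and 2.47 ± 0.21, and Hk3, a hexokinase of myeloid cells, by 2.92 ± 0.26. Kupffer cell genes (11 of 12 higher, median 2.01) and cell cycle genes (20 of 22, 21 alone, median 3.18) held with an estimated correlation, both at 0.0196. Matrix genes (13 of 25, 14 alone), myofibroblast genes (4 of 17, 8 alone), lymphocytes (13 of 18, 16 alone), monocyte-derived macrophages (9 of 17, 10 alone) and blood genes (4 of 7) were called higher and had adjusted p of 0.483, 0.483, 0.158, 0.270 and 0.158 with an estimated correlation. T3 targets were not called (3 of 15 higher and 1 lower, list adjusted p = 0.0568). Of 2926 genes called 1658 were higher and 1268 lower, and 1657 and 691 when scaled by total counts alone.

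The genotypes differed in the T3 response without injury for 1906 genes, 871 with a higher and 1035 with a lower response in knockouts. Dio1 differed by -6.53 ± 0.48, Gpd2 by -3.85 ± 0.28, Thrsp by -4.95 ± 0.79 and Stim2, a calcium sensor, by -3.12 ± 0.22 (adjusted p = 2.67e-10). Dnah11, a dynein of cilia, differed by -9.31 ± 0.69. Lgals1, a galectin made by stromal cells, differed by 2.42 ± 0.30. The T3 target list was lower (10 of 15, 11 alone, median -2.48, list adjusted p = 5.03e-15, 2.37e-04 with an estimated correlation). Cytochrome P450 genes (8 of 19 higher and 1 lower, 10 and 1 alone) and myofibroblast genes (5 of 17) were called higher, with 0.481 for both with an estimated correlation. Matrix, quiescent stellate and fatty acid oxidation genes were also called higher and cell cycle (2 of 22, median -0.61), cholesterol synthesis and lipogenesis genes lower, at 0.789 to 0.959 with an estimated correlation. The cell cycle call ended without knockout T3 oil replicate 2 (0.175) or wild-type T3 oil replicate 1 (0.0914) or 2 (0.0522), and the stellate and fatty acid oxidation calls without single libraries (0.0506 to 0.102). Kupffer cell genes were not called.

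T3 in injured wild-type mice lowered part of the fibrosis, myeloid and stress genes and raised T3 targets and genes of bile acid, lipid and energy metabolism. Of these lists only the T3 targets held with an estimated correlation. Timp1 fell from 15.5 ± 9.70 to 1.87 ± 0.361 CPM (-3.05 ± 0.46, adjusted p = 6.90e-06). Tagln fell from 20.9 ± 12 to 6.05 ± 1.97 CPM (-1.78 ± 0.36, adjusted p = 2.42e-04). Loxl2 (-1.22 ± 0.25), Postn, a matrix protein of activated fibroblasts (-1.10 ± 0.22), and Ccn1, a matricellular protein (-2.50 ± 0.35), fell as well. So did Cd14 (-3.72 ± 0.51), Ccl2, which recruits monocytes (-2.62 ± 0.58), and Trib3, a gene of the integrated stress response (-4.72 ± 0.68). Sox9, a transcription factor of bile duct cells, changed by -2.06 ± 0.32, Areg, a growth factor of wounded tissue, by -5.81 ± 1.12, and Nupr1, a stress-induced nuclear protein gene, by -5.64 ± 1.09. Lcn2 was called lower (-1.63 ± 0.60, adjusted p = 0.0292), and this call ended without wild-type T3 CCl4 replicate 1, 3 or 4 or without wild-type PBS CCl4 replicate 2 or 3. Thrb rose (0.79 ± 0.21, adjusted p = 3.80e-03) and was not called when scaled by total counts alone.

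Myofibroblast genes (11 of 17 lower, median -0.997, list adjusted p = 0.00180), TGF-β targets (7 of 14 lower and 1 higher, median -0.59, 0.0116), matrix genes (11 of 25 lower and 1 higher, median -0.59, 0.0195), neutrophils (9 of 10 lower, median -2.71, 0.0106), monocyte-derived macrophages (7 of 17 lower and 2 higher, 0.0369), cholangiocytes (10 of 12 lower and 1 higher, 0.00986) and stress genes (10 of 15 lower, 6.94e-04) were called lower by T3 in injured wild-type mice. With an estimated correlation none held, at 0.275, 0.203, 0.586, 0.430, 0.432, 0.287 and 0.203. The matrix call ended without wild-type T3 CCl4 replicate 1 (0.111) and without wild-type PBS CCl4 replicate 1 (0.0864) or 4 (0.0889). Wild-type PBS CCl4 replicate 2 stood apart on the neutrophil list, with a mean log2 CPM of 4.10, and without it the median of that list was -1.17 (0.0427). The monocyte call ended without wild-type T3 CCl4 replicate 1 (0.0817) or wild-type PBS CCl4 replicate 2 (0.0530). When scaled by total counts alone, matrix (0.0647), monocyte (0.229), neutrophil (0.0629) and cholangiocyte genes (0.0547) were not called. Members that rose against their lists included Col12a1 (1.15 ± 0.27), Fabp5, a fatty acid carrier of macrophages (2.07 ± 0.54), and Prom1, a surface gene of progenitor cells (3.24 ± 0.47). Matrix-degrading enzymes were not called as a list (11 of 20 lower and 2 higher, list adjusted p = 0.0756), with Mmp19, a matrix protease, and Ctsd, a lysosomal protease, higher by 1.07 ± 0.18 and 0.73 ± 0.16. Quiescent stellate cell, sinusoidal endothelium and acute-phase genes were not called (adjusted p of 0.529, 0.367 and 0.414).

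Dio1 rose in injured wild-type livers from 0.726 ± 0.247 to 1005 ± 123 CPM (10.41 ± 0.43, adjusted p = 1.90e-16) and Thrsp by 6.43 ± 0.67. Timd4 rose by 2.48 ± 0.29, Clec4f by 2.34 ± 0.31 and Rrm2 by 2.24 ± 0.34. Cyp7b1, an enzyme of bile acid synthesis, rose by 3.42 ± 0.33, Sc5d, of cholesterol synthesis, by 2.83 ± 0.34, Fasn, the fatty acid synthase, by 3.58 ± 0.49, Arg1, the last enzyme of the urea cycle, by 1.86 ± 0.22, and Cyc1, a respiratory chain subunit, by 0.99 ± 0.11. Wfdc16, a gene of the protease inhibitor family, had no counts on PBS and rose at least 755.2-fold. T3 targets (12 of 15 higher, list adjusted p = 1.95e-14) held with an estimated correlation (2.71e-04). Kupffer cells (11 of 12, 12 alone), lymphocytes (7 of 18, 6 alone), cell cycle (8 of 22), bile acid handling (10 of 14), cholesterol synthesis (20 of 20), lipogenesis (12 of 15, 15 alone), oxidative phosphorylation (18 of 18), pericentral (11 of 15 higher and 1 lower) and periportal genes (10 of 14 higher and 3 lower), secreted proteins (9 of 12, 11 alone) and blood genes (2 of 7) were also called higher. They did not hold with an estimated correlation (0.203 to 0.506). Members that fell against the zonal lists included Oat, an ornithine enzyme (-1.53 ± 0.42), Etnppl, a phospholipid enzyme (-2.40 ± 0.47), and Hsd17b6, a steroid dehydrogenase (-2.58 ± 0.60). Cytochrome P450 genes (5 of 19 higher and 6 lower, adjusted p = 0.697) and fatty acid oxidation (0.0846) were not called as lists.

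T3 changed 6506 genes in injured wild-type mice, 3116 higher and 3390 lower. Scaled by total counts alone, 1670 were higher and 6564 lower, and with only the compared groups in the fit 4194 were called. The T3 effects with and without CCl4 shared 1477 rises and 1016 falls in wild type, where 593.3 and 550.0 would be shared by independent lists, and 254 genes went opposite ways.

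**Figure D2:**
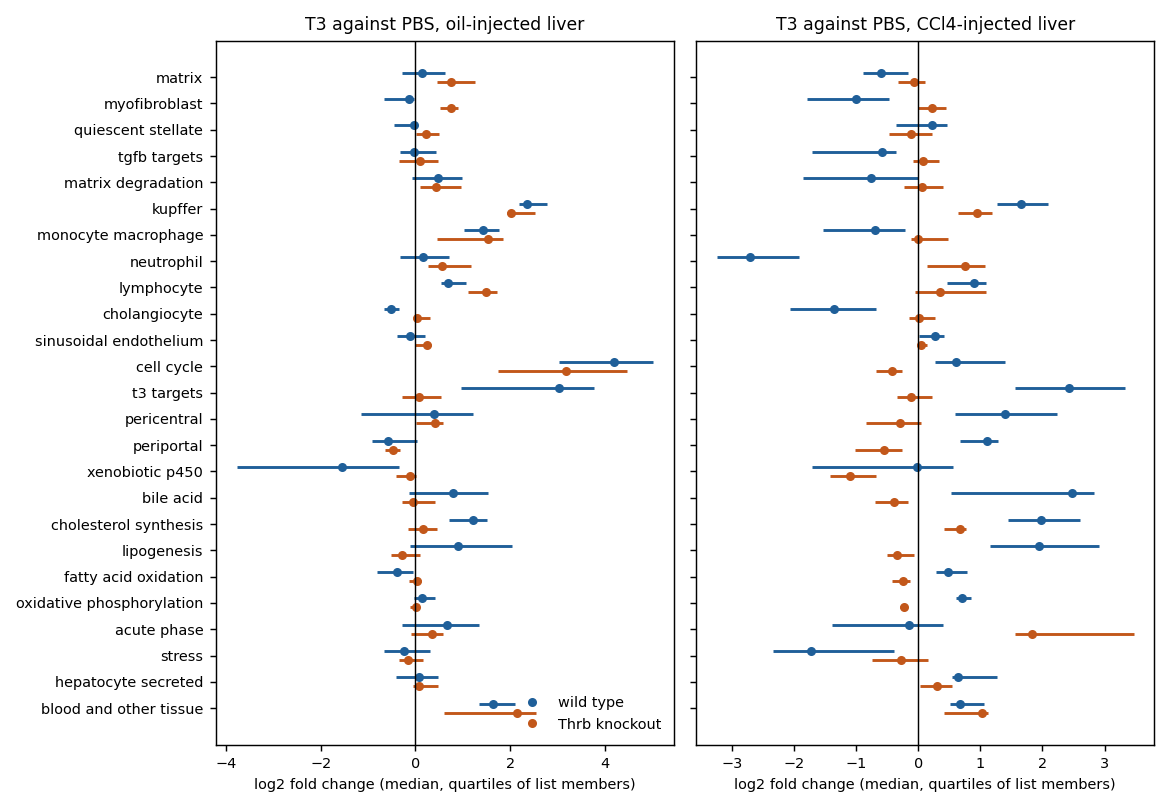
Median and quartiles of the log2 fold change, T3 against PBS, over the members of each list on oil (left) and on CCl4 (right), in wild type (blue) and knockout (orange). The median of the T3 targets was 3.02 on oil and 2.43 on CCl4 in wild type, and 0.07 and -0.11 in knockouts.

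The T3 response of wild-type mice differed between CCl4 and oil for 3722 genes, 1684 with a higher and 2038 with a lower response on CCl4, and 621 and 5382 when scaled by total counts alone. Cell cycle genes responded less (19 of 22 lower, 20 alone, median -3.13), with Cdk1 at -4.25 ± 0.58. Monocyte-derived macrophage genes (12 of 17 lower, 13 alone), matrix genes (6 of 25) and stress genes (7 of 15, 11 alone) also had a lower response on CCl4, and oxidative phosphorylation a higher one (13 of 18 higher and 1 lower, 15 and 1 alone). With an estimated correlation these lists had adjusted p of 0.137, 0.137, 0.480, 0.137 and 0.287. TGF-β target, matrix-degrading, Kupffer cell and neutrophil genes were also called lower and the other hepatocyte lists higher, at 0.208 to 0.480. The genes with the smallest adjusted p were Rsad2, Xaf1, Oasl2 and Ifit3, antiviral genes induced by interferon, at -4.41 ± 0.43, -2.92 ± 0.29, -3.08 ± 0.33 and -3.41 ± 0.37.

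T3 in injured knockout mice raised acute-phase genes. Lcn2 rose from 72.1 ± 28.3 to 2109 ± 1310.0 CPM (4.87 ± 0.68, adjusted p = 1.18e-04), Saa3, a serum amyloid gene, by 3.73 ± 0.46 (adjusted p = 3.39e-05) and Hp, which binds free haemoglobin, by 2.61 ± 0.36. Dio1 rose by 3.27 ± 0.31 (adjusted p = 2.63e-07), Slc37a1, a sugar-phosphate carrier, by 2.19 ± 0.27 and the transcribed pseudogene 9030619P08Rik by 4.01 ± 0.44. Acute-phase genes as a list (16 of 18 higher, 18 alone, median 1.83, list adjusted p = 2.40e-45) held with an estimated correlation (7.08e-04). Matrix genes (adjusted p = 0.413), myofibroblast genes (0.287) and TGF-β targets (0.287) were not called and had no called member. For myofibroblast genes the median was 0.22, the mean -0.01, and the test pointed up. T3 targets were not called either (1 of 15 higher and 1 lower, 2 and 1 alone, adjusted p = 0.287), with a median of -0.11, a mean of -0.06 and a test that pointed up. Kupffer cell genes (4 of 12 higher, 11 alone) were called higher and cytochrome P450 genes (3 of 19 lower and 1 higher, 14 and 1 alone) lower, with adjusted p of 0.208 and 0.446 with an estimated correlation. Lymphocyte, cholesterol synthesis, secreted protein and blood genes were also called higher and cell cycle, periportal, fatty acid oxidation and oxidative phosphorylation genes lower, at 0.514 to 0.652. Secreted proteins (median 0.31, 1 of 12 higher, 3 higher and 1 lower alone) were not called without knockout PBS CCl4 replicate 3 (0.500), nor blood genes (0.150). Cell cycle, periportal and fatty acid oxidation calls also ended without single libraries (0.0510 to 0.364).

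Of 396 genes called for T3 in injured knockout mice 276 were higher and 120 lower, and 179 and 239 when scaled by total counts alone. DESeq2 called 681, and 85 were called with only the compared groups in the fit. The count fell to 165 without knockout T3 CCl4 replicate 4, 176 without replicate 2, 189 without knockout PBS CCl4 replicate 1 and 237 without replicate 4. It was 591 without knockout PBS CCl4 replicate 3 and 1160 without the 2 libraries farthest from their groups.

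The interaction of T3 and genotype on CCl4 asked whether the T3 response of injured livers depended on the receptor gene. Fibrosis genes that fell with T3 in wild type were not called lower in knockouts, and acute-phase genes rose with T3 in knockouts. Hormone targets and genes of bile acid, lipid and energy metabolism responded less in knockouts. As lists for this difference only the T3 targets held with an estimated correlation. Timp1 differed by 3.50 ± 0.61 (adjusted p = 1.70e-04), with 8.41 ± 5.19 CPM on PBS and 11.4 ± 1.52 on T3 in knockouts. Tagln differed by 2.38 ± 0.49 (adjusted p = 8.77e-04). Col4a1, a basement membrane collagen, differed by 1.31 ± 0.30 and Ccl2 by 3.77 ± 0.79. Acta2, the smooth muscle actin of myofibroblasts, differed by 2.65 ± 0.79 (adjusted p = 0.0160), a call that ended without wild-type PBS CCl4 replicate 2. Lcn2 differed by 6.50 ± 0.90, Saa3 by 5.21 ± 0.62 and Mt2, a metal-binding protein gene, by 7.63 ± 1.14. On the other side Dio1 differed by -7.14 ± 0.46 (adjusted p = 2.95e-11), Thrsp by -6.80 ± 0.82, Cyp7a1, the first enzyme of bile acid synthesis, by -9.14 ± 1.43, Slc22a7, an organic anion carrier, by -9.79 ± 0.75, Rrm2 by -2.90 ± 0.48 and Cyc1 by -1.29 ± 0.16. Elovl3, a fatty acid elongase, was at 7.04 ± 0.654 CPM in wild-type T3 CCl4 livers and had no counts in knockout T3 CCl4 livers.

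As lists, myofibroblast genes (8 of 17 with a higher response in knockouts, median 0.81, list adjusted p = 2.95e-04), TGF-β targets (5 of 14, 8 alone, 0.00200), matrix-degrading enzymes (9 of 20 higher and 2 lower, 0.0211), neutrophils (7 of 10), monocyte-derived macrophages (6 of 17 higher and 1 lower), cholangiocytes (4 of 12 higher and 1 lower, 5 and 1 alone), acute-phase (17 of 18) and stress genes (6 of 15) were called for the difference between genotypes on CCl4. Matrix genes were not (5 of 25 higher and 1 lower, 7 and 1 alone, adjusted p = 0.0570). T3 targets (11 of 15 lower, 13 alone, median -2.50, list adjusted p = 7.36e-16), cell cycle (6 of 22), pericentral (10 of 15) and periportal genes (8 of 14, 9 alone), bile acid handling (10 of 14, 11 alone), cholesterol synthesis (12 of 20, 13 alone), lipogenesis (12 of 15, 13 alone), oxidative phosphorylation (18 of 18), fatty acid oxidation (3 of 18, with 5 lower and 1 higher alone), secreted proteins (5 of 12) and Kupffer cells (1 of 12) had a lower response. Only the T3 targets held with an estimated correlation (2.15e-04). The other called lists ran from 0.0747 to 0.431, with myofibroblast genes at 0.228 and TGF-β targets at 0.149. Matrix-degrading enzymes lost their call without knockout T3 CCl4 replicate 1 (0.0546) or wild-type T3 CCl4 replicate 1 (0.0595), and with scaling by total counts alone (0.0544). In that scaling monocyte-derived macrophages lost theirs too (0.0579). For blood genes the median was 0.33 and the mean -0.84, the test pointed down and the adjusted p was 0.341. In all, 3538 genes were called, 1603 with a higher and 1935 with a lower response, 2593 and 1241 when scaled by total counts alone, and 2287 with only the compared groups in the fit.

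Compared on T3 and CCl4, knockout livers held more of many myofibroblast genes than wild-type livers, and lists of other cells and of injury moved alongside. Tagln was at 40.6 ± 14.9 CPM against 6.05 ± 1.97 (2.75 ± 0.37, adjusted p = 3.89e-06), Timp1 at 11.4 ± 1.52 against 1.87 ± 0.361 (2.62 ± 0.46, adjusted p = 1.31e-04) and Acta2 at 14.2 ± 6.06 against 1.81 ± 0.969 (2.97 ± 0.60, adjusted p = 6.14e-04). Mmp13, a collagenase, was higher by 2.78 ± 0.56, Cd14 by 2.77 ± 0.49, Apcs, an acute-phase pentraxin, by 3.29 ± 0.44, Fam83a, a growth factor signalling gene, by 5.31 ± 0.60, and Serpina7, a carrier of thyroid hormone in blood, by 4.49 ± 0.66. Dio1 (-3.14 ± 0.30), Thrsp (-5.36 ± 0.64) and Cyp7a1 (-6.44 ± 1.10) were lower. Elovl3 was at least 206.0-fold lower.

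In that comparison myofibroblast genes (10 of 17 higher, 11 alone, list adjusted p = 9.22e-07), TGF-β targets (9 of 14 higher and 1 lower, 10 and 1 alone, 1.38e-04), matrix genes (10 of 25 higher and 1 lower, 0.00680) and acute-phase genes (14 of 18, 15 alone, 5.24e-08) were called higher, and T3 targets (11 of 15 lower, 2.14e-10) and oxidative phosphorylation (18 of 18 lower, 1.49e-17) lower. With an estimated correlation the adjusted p was 0.137, 0.0750, 0.472, 0.197, 0.00276 and 0.0750. The matrix call ended without knockout T3 CCl4 replicate 1 (0.0504) or wild-type T3 CCl4 replicate 1 (0.0823). Col12a1 was lower (-1.05 ± 0.27) and Kupffer cell genes were called lower (4 of 12, 8 alone, list adjusted p = 0.00465, 0.450 with an estimated correlation). Matrix-degrading (7 of 20 higher and 2 lower, 11 and 2 alone), macrophage, neutrophil (2 of 10, 5 alone), cholangiocyte and stress genes (6 of 15, 8 alone) were also called higher in knockouts, and pericentral (12 of 15), periportal, bile acid (10 of 14, 11 alone), lipogenesis, cholesterol, cell cycle, lymphocyte and P450 genes lower. None of these held with an estimated correlation (0.137 to 0.455). Calls ended without knockout T3 CCl4 replicate 1 for matrix-degrading enzymes and lymphocytes (0.0504 for both), without knockout T3 CCl4 replicate 4 or with total counts alone for neutrophils (0.0554 and 0.0562), and without wild-type T3 CCl4 replicate 1 for matrix-degrading enzymes (0.0719) and P450 genes (0.190). Of 3566 genes called 1621 were higher and 1945 lower in knockouts, and 2153 and 1379 when scaled by total counts alone.

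**Figure D3:**
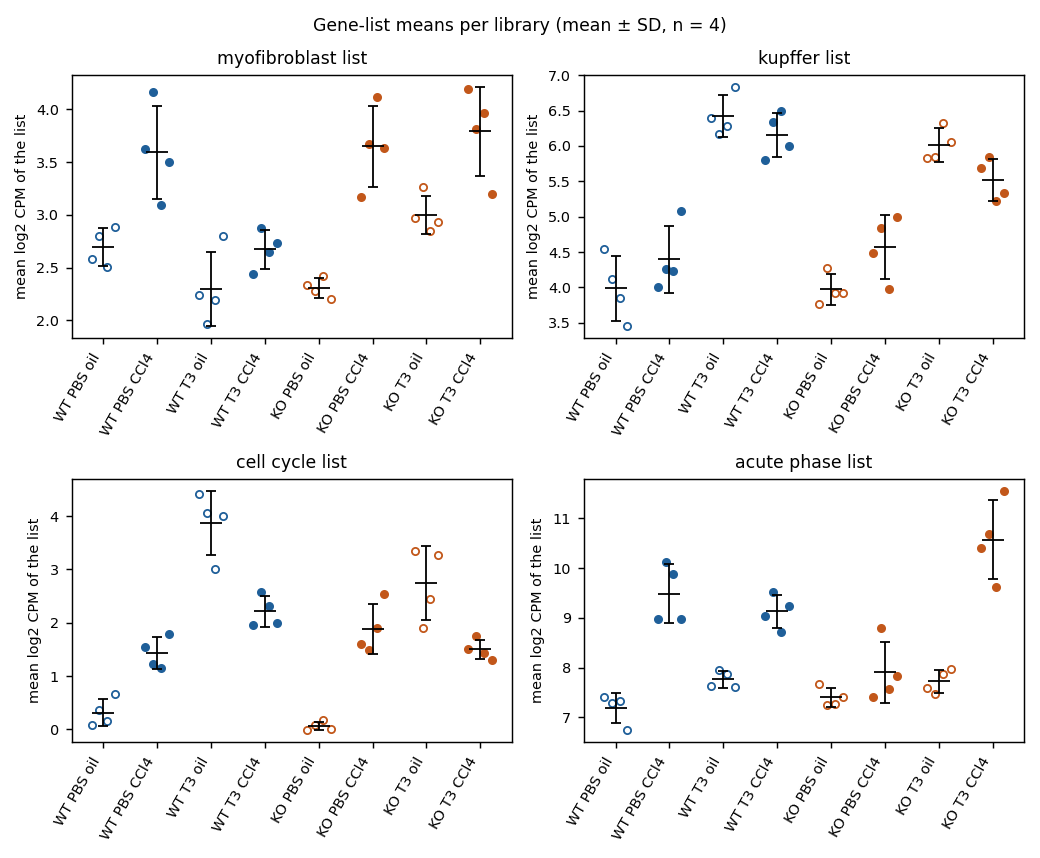
Mean log2 CPM of the myofibroblast, Kupffer cell, cell cycle and acute-phase lists in each of the 32 libraries, by group, with open points for oil, filled points for CCl4, blue for wild type and orange for knockout. The median change of the Kupffer cell list with T3 on oil was 2.36 in wild type and 2.01 in knockouts.

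Compared with oil on T3, CCl4 changed 531 genes in wild type, 260 higher and 271 lower, and 88 and 268 when scaled by total counts alone. Aspm, Ccnb1, Ccnb2 and Cenpe, genes of mitosis, fell, with changes of -3.44 ± 0.44, -4.12 ± 0.53, -2.98 ± 0.39 and -3.57 ± 0.47, each at an adjusted p of 7.59e-05. Lcn2 rose by 3.55 ± 0.65 and Cd63 by 2.11 ± 0.37. Cell cycle genes (13 of 22 lower, 14 alone) held with an estimated correlation (0.0424), and acute-phase genes (4 of 18 higher, 9 alone) did not (0.222). Also called higher were monocyte-derived macrophages (3 of 17, list adjusted p = 0.00163), cytochrome P450 genes (3 of 19 higher and 1 lower, 7 and 1 alone, 0.00318), myofibroblast genes (1 of 17, 0.0473) and matrix-degrading enzymes (0 of 20, 1 alone, 0.0473). These had adjusted p of 0.705, 0.768, 0.807 and 0.768 with an estimated correlation. The myofibroblast call ended without wild-type T3 CCl4 replicate 2 (0.0864) or 4 (0.112), or wild-type T3 oil replicate 1 (0.0868), 2 (0.222) or 3 (0.0501). The call for matrix-degrading enzymes ended without wild-type T3 CCl4 replicate 2 (0.0606) or 4 (0.144), or wild-type T3 oil replicate 1 (0.115) or 2 (0.222), and the P450 call without wild-type T3 oil replicate 4 (0.0662). Both ended with only the compared groups in the fit (0.0893), and matrix-degrading enzymes without the 2 farthest libraries (0.0626). The count was 328 without wild-type T3 oil replicate 4, 347 without wild-type T3 CCl4 replicate 1 and 345 without replicate 2. In knockouts on T3, CCl4 changed 6175 genes, 3080 higher and 3095 lower, and 3897 and 2167 when scaled by total counts alone. There Golm1, a Golgi membrane gene of injured hepatocytes, rose by 2.40 ± 0.19 (adjusted p = 8.81e-09), P3h1, a collagen-modifying enzyme, by 1.73 ± 0.15, Cyb561, an electron carrier, by 2.49 ± 0.22, Tagln2 by 1.73 ± 0.16, Lcn2 by 7.05 ± 0.76 and Timp1 by 4.42 ± 0.52. Acute-phase genes (17 of 18) and myofibroblast genes (8 of 17 higher and 1 lower, 9 and 1 alone) were called higher and cell cycle genes (14 of 22 lower and 2 higher, 14 and 3 alone) lower, at 0.177, 0.257 and 0.273 with an estimated correlation. Another 19 lists were called, among them hepatocyte lists lower and macrophages, neutrophils and stress genes higher, and none held (0.177 to 0.418). Ccne1 and Ccnd1, cyclins of early cycle phases, were the cell cycle genes that rose (2.16 ± 0.43 and 1.32 ± 0.35).

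Without T3 the knockout changed fewer genes. On PBS and oil 84 genes were called, 63 higher and 21 lower in knockouts, against 144 with DESeq2, 160 without the 2 libraries farthest from their groups and 47 without wild-type PBS oil replicate 2. Gpd2 was higher by 2.41 ± 0.20 (adjusted p = 2.05e-08), Slc25a45, a mitochondrial carrier, by 1.95 ± 0.19 and Dio1 by 3.30 ± 0.38 (adjusted p = 6.32e-06). The pseudogene 9030619P08Rik had 3 counts in wild type and a ratio of 197.1 (95% counting interval 67.1 to 958.4). T3 targets were higher as a list (3 of 15, 7 alone, list adjusted p = 2.01e-16) and held with an estimated correlation (1.22e-04). Matrix (0 of 25, median -0.33) and myofibroblast genes (1 of 17, -0.25) were called lower and lipogenesis (1 of 15, 7 alone) higher, at 0.959, 0.585 and 0.428 with an estimated correlation. The matrix call ended without wild-type PBS oil replicate 4 (0.150).

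On PBS and CCl4 351 genes were called between genotypes, 189 higher and 162 lower in knockouts, and 109 and 246 when scaled by total counts alone. Dio1 was higher by 3.996 ± 0.35 (adjusted p = 4.92e-08), Slc25a45 by 1.72 ± 0.19 and 9030619P08Rik by 6.37 ± 0.72. Lcn2 (-3.38 ± 0.64, adjusted p = 0.00424) and Saa1 (-4.74 ± 0.81) were lower. T3 targets were higher as a list (2 of 15, 9 alone) and held with an estimated correlation (0.00136), and acute-phase genes were lower (5 of 18, 12 alone) and did not (0.137). Neutrophils (4 of 10, 6 alone) and lymphocytes were called lower and cell cycle, periportal, bile acid, cholesterol, lipogenesis, fatty acid oxidation, oxidative phosphorylation and secreted protein genes higher, at 0.241 to 0.570 with an estimated correlation. Of these the lymphocyte and cell cycle calls ended without single libraries (0.101 to 0.272). Matrix, myofibroblast and TGF-β genes were not called as lists. The count ran from 70 without wild-type PBS CCl4 replicate 2 to 1748 without replicate 4. DESeq2 called 731, 205 were called without the filter on low counts, 209 without the 2 libraries farthest from their groups and 3 with only the compared groups in the fit.

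On T3 and oil 2549 genes were called between genotypes, 1113 higher and 1436 lower in knockouts, and 759 and 1829 when scaled by total counts alone. Lower genes included Dnah11 (-7.49 ± 0.34, adjusted p = 3.25e-15), Lrrc8b, a volume-regulated channel subunit (-3.97 ± 0.22), Cep126, of the cilium base (-7.94 ± 0.46) and Dio1 (-3.23 ± 0.30). T3 targets (9 of 15 lower, 11 alone) held with an estimated correlation (0.0166). Cytochrome P450 genes (10 of 19 higher and 1 lower, 11 and 2 alone) were called higher and cell cycle genes (10 of 22, 15 alone) lower, at 0.297 and 0.730 with an estimated correlation. Myofibroblast genes (3 of 17, 6 alone, median 0.49, list adjusted p = 0.00580), matrix genes (3 of 25 higher and 1 lower, 5 and 1 alone, median 0.50, 0.0255) and fatty acid oxidation (4 of 18, 5 alone, 0.00580) were also called higher and cholesterol synthesis (5 of 20, 11 alone, 1.29e-04) lower. They had adjusted p of 0.854, 0.906, 0.906 and 0.906 with an estimated correlation. Without wild-type T3 oil replicate 4 the myofibroblast median was 0.87. The matrix call ended without knockout T3 oil replicate 1 (0.0554) or wild-type T3 oil replicate 1 (0.0534) or 2 (0.146). Cyp2e1 was at 4133 ± 354 CPM in knockouts and 1072 ± 193 CPM in wild type.

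**Figure D4:**
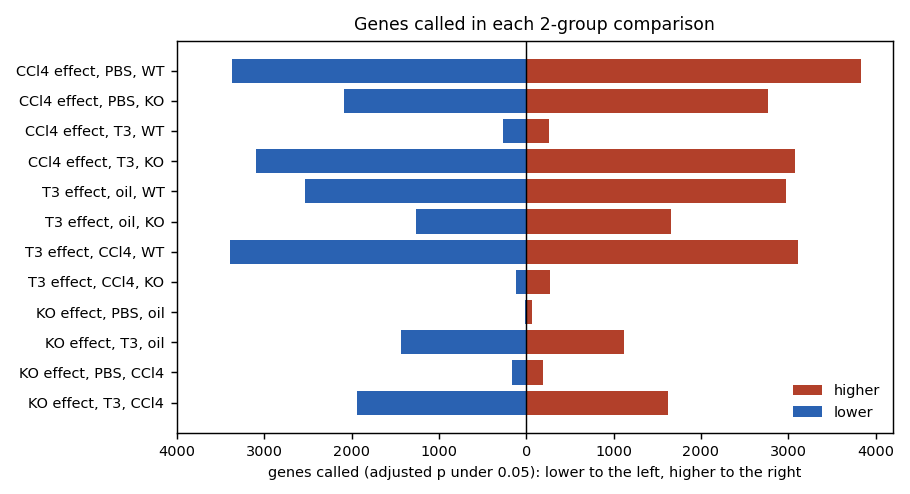
Number of genes called higher and lower at an adjusted p of 0.05 in each of the 12 comparisons between 2 groups, out of 15599 tested. T3 on CCl4 changed 6506 genes in wild type and 396 in knockouts.

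The share of injury genes that T3 moved back was 43.4% in wild type, with 2107 of the 4854 genes chosen in knockouts moving opposite to CCl4, against 1018.3 for independent lists (exact 95% interval 42.01% to 44.8%, over genes that are not independent replicates). Another 384 moved the same way as CCl4. Genes raised by CCl4 had a median T3 change of -0.46 and genes lowered by it 0.42. In knockouts the share was 0.583%, with 42 of the 7201 genes chosen in wild type (exact 95% interval 0.421% to 0.788%), against 89.1 for independent lists, and 155 moved the same way as CCl4. The wild-type share was 56.9% when scaled by total counts alone, and 32.2% with only the compared groups in the fit. The knockout share was 1.16% with DESeq2, 1.17% without the 2 libraries farthest from their groups, 0.0654% with only the compared groups in the fit, 0.194% without knockout T3 CCl4 replicate 4, 0.208% without replicate 2 and 0.361% without knockout PBS CCl4 replicate 1. On CCl4 the genotypes shared 132 T3 rises and 45 falls, against 55.1 and 26.1 for independent lists, and 40 genes went opposite ways. On oil they shared 1167 rises and 397 falls, against 315.7 and 205.7, and 80 went opposite ways.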

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

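The tests of explanations in this part were all chosen after the results were seen, and the counts of other splits of the libraries were planned.

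Single libraries stood apart in 17 of 224 tests, each of a list's mean level, a receptor gene or the total counts within 1 group of 4 mice. In each the gap to the nearest neighbour, as a share of the group's range, passed 0.829. Chance gives about 1 in 20, so a gap alone says nothing about a library. Wild-type PBS CCl4 replicate 2 and knockout PBS CCl4 replicate 3 were also the farthest from their groups. The neutrophil list was highest in knockout T3 CCl4 replicate 4 (0.924), wild-type T3 CCl4 replicate 4 (0.890) and wild-type PBS CCl4 replicate 2 (0.879). The cytochrome P450 list was highest in wild-type T3 CCl4 replicate 1 (0.929) and knockout PBS oil replicate 4 (0.913) and lowest in knockout PBS CCl4 replicate 3 (0.910). The bile acid list was lowest in knockout PBS CCl4 replicate 3 (0.931) and wild-type T3 oil replicate 4 (0.834), and highest in wild-type PBS oil replicate 1 (0.869). The oxidative phosphorylation list was lowest in knockout T3 oil replicate 2 (0.887) and highest in wild-type PBS oil replicate 1 (0.934). Fatty acid oxidation was lowest in knockout T3 oil replicate 2 (0.918), and lipogenesis highest in knockout PBS CCl4 replicate 4 (0.944). Sinusoidal endothelium was lowest in wild-type T3 oil replicate 1 (0.926) and wild-type PBS oil replicate 2 (0.849). Thrb was highest in wild-type T3 oil replicate 3 (0.939) and Thra lowest in knockout T3 CCl4 replicate 4 (0.935).

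In interaction tests the T3 response differed between genotypes for 1906 genes on oil and 3538 on CCl4. The CCl4 response on PBS differed for 3, and wild-type T3 responses differed between CCl4 and oil for 3722. The T3 target list differed between genotypes by a median log2 of -2.48 on oil and -2.50 on CCl4.

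Other splits of the same libraries were counted with only the compared groups in the fit. For 10 of the 12 comparisons between groups the real split was the 1 of 35 with the most genes called by edgeR. This smallest possible share cannot exclude chance. The real count and the highest of the other splits were 4590 and 0 for CCl4 in wild-type PBS mice, 3449 and 0 in knockout PBS mice, 784 and 6 for CCl4 in wild-type T3 mice, and 6324 and 0 in knockout T3 mice. For T3 they were 6173 and 0 in wild type on oil, 2964 and 2 in knockouts on oil, and 4194 and 1 in wild type on CCl4. For the knockout they were 117 and 11 on PBS and oil, 2790 and 0 on T3 and oil, and 4629 and 0 on T3 and CCl4.

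Chance stays open for the other 2 comparisons too, where 2 of 35 splits gave as many genes. For T3 in injured knockouts the real split gave 85 genes and another 221, with knockout T3 CCl4 replicate 1 and knockout PBS CCl4 replicates 1, 2 and 4 against the rest. For the knockout on PBS and CCl4 the real split gave 3 and another 961, with knockout PBS CCl4 replicates 1, 2 and 4 and wild-type PBS CCl4 replicate 4 against the rest. That split points to a structure of the samples other than genotype. Of 100 drawn splits per interaction, the real one included, 1 gave as many genes for T3 by genotype on oil (real 2675, highest other 851). It was 1 on CCl4 (2287 and 653) and 2 for T3 by CCl4 in wild type (2903 and 3086). These draws shuffled genotype, or CCl4 and oil, within each hormone arm. That removes the factor's whole effect, not the interaction alone, so chance cannot be excluded. The split with 3086 kept the wild-type PBS CCl4 group whole. For CCl4 by genotype on PBS all 100 gave at least the real count of 0 (highest 667, edgeR, with 1242 genes at an unadjusted p below 0.05 and 4 called by DESeq2 when all groups were fitted), so they say nothing about it.

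The first pattern weighed was that matrix, myofibroblast and TGF-β target genes were lower with T3 in injured wild-type liver, with a genotype difference for the myofibroblast and TGF-β lists. With an estimated correlation none of these calls held (0.586, 0.275 and 0.203 for the fall, and 0.228 and 0.149 for the difference). A single library is argued against as the source of the whole pattern. With all libraries 29 of the 56 list members were called lower, and at least 21 whichever library was left out, the fewest without wild-type PBS CCl4 replicate 2 or wild-type T3 CCl4 replicate 1. The matrix list alone lost its call without single libraries (0.0864 to 0.111). A higher share of hepatocyte RNA with T3 as the whole cause would lower all other cell types alike. Cholangiocyte and neutrophil genes did fall and secreted hepatocyte proteins rose, but the lower quartile of the sinusoidal endothelial list, not called with T3 on oil, was 0.0104, above the upper quartiles of the 3 lists (-0.16 at most). Stronger injury in the wild-type PBS mice as the whole cause is argued against by the knockouts compared with wild type on T3 and CCl4, where the lower quartile of the myofibroblast list was 0.54. It may account for a part, since on PBS and CCl4 acute-phase and neutrophil genes were called lower and several hepatocyte lists higher in knockouts, though not with an estimated correlation (0.137 to 0.553). Whether the difference needs injury was left open. On T3 and oil the myofibroblast and matrix lists were called higher in knockouts too (0.00580 and 0.0255, and 0.854 and 0.906 with an estimated correlation), the matrix call ending without any 1 of 3 libraries (0.0534 to 0.146), and the TGF-β list was not called (0.811). The dependence on Thrb may be biological, as a hypothesis, and a difference in library kit and a weaker injury in the wild-type T3 mice stay open, since no value here decides them.

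The second pattern was that Kupffer cell and cell cycle genes were higher with T3 in oil-injected liver of both genotypes. More blood in the T3 livers could raise some cell genes, and haemoglobin genes did rise. The most abundant neutrophil genes, S100a8 and S100a9, changed by 0.49 at most, below the lower quartiles of the Kupffer cell list of 2.19 in wild type and 1.94 in knockouts. A lower share of hepatocyte RNA would raise all other cell lists alike. The upper quartiles of the sinusoidal endothelial, cholangiocyte and quiescent stellate lists reached 0.50 at most, below the lower quartiles of the Kupffer cell list, so the lists moved apart. Macrophage and lymphocyte genes were called higher in both genotypes and matrix and myofibroblast genes in knockouts, none of them with an estimated correlation (0.158 to 0.846). The wild-type lymphocyte call ended without any 1 of 4 libraries (0.0513 to 0.125). More Kupffer cells, or more RNA per cell, and proliferation of any cell type stay open, since bulk RNA does not name the cells.

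The third pattern was that acute-phase genes were higher with T3 in injured knockout liver. A single library is argued against, since the lowest list median with any library left out was 1.56, without knockout T3 CCl4 replicate 4. The counts of the 10 most abundant genes could raise all others by a log2 of 0.0288 at most between any T3 and PBS library, below the list's lower quartile of 1.55. A swap of knockout libraries between hormone arms is argued against by Dio1, whose lowest level with T3 was 3.86 times the highest with PBS. The list's mean log2 CPM was 7.90 on PBS and 10.58 on T3 in injured knockouts, 9.49 and 9.13 in wild type. A low PBS level may thus be part of the rise. Infection or injury severity may also raise these genes and was not tested.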

How the results depend on the processing

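Scaling by total counts alone and leaving out the 2 libraries farthest from their groups were chosen after the data were seen, and the other alternatives were planned. No named gene or list called in the results changed direction under the alternatives run for it. Lists were not tested with DESeq2, and the estimated correlation applies to lists alone. The balance of rises and falls among the genes called did turn over in some comparisons. With total counts alone it did so in 5: T3 in injured knockouts (276 higher and 120 lower to 179 and 239), the knockout on PBS and CCl4 and on T3 and CCl4, T3 by genotype on CCl4, and CCl4 in knockout T3 mice. Without the 2 farthest libraries it did so in 4, among them T3 in injured wild type (3116 and 3390 to 2921 and 2802) and in injured knockouts (to 557 and 603), and with only the compared groups in 3, among them T3 in injured wild type (2178 and 2016). DESeq2, no filter and the block turned over 1 each, and 7 of the single libraries left out turned over 1 and 1 turned over 2.

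DESeq2 called 681 genes for T3 in injured knockouts, 144 for the knockout on PBS and oil and 731 on PBS and CCl4, and gave a share moved back by T3 of 1.16% in knockouts. Without the filter on low counts the knockout changed 205 genes on PBS and CCl4. With scaling by total counts alone T3 by CCl4 in wild type gave 6003 genes, 621 higher and 5382 lower, and the share moved back in wild type was 56.9%. That scaling moved the median log2 change of all genes to 0.43 for CCl4 in wild-type PBS mice, 0.35 in knockout PBS mice, -0.42 for T3 in injured wild type, 0.30 for T3 by genotype on CCl4 and -0.53 for T3 by CCl4. It lay from -0.13 (T3 in injured knockouts) to 0.17 (knockout on T3 and CCl4) elsewhere. These medians follow the TMM factors left out (means of 1.21 in wild-type PBS CCl4 and 0.92 in wild-type PBS oil livers). What set them, and the cause of the other changes, was not tested.

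Without the 2 farthest libraries 1160 genes were called for T3 in injured knockouts, 160 for the knockout on PBS and oil, 209 for the knockout on PBS and CCl4 and 0 for CCl4 by genotype (edgeR, where all libraries gave 3, with 1242 at an unadjusted p below 0.05, and DESeq2 4). The shares moved back were 38.7% in wild type and 1.17% in knockouts. With only the compared groups in the fit, CCl4 in wild-type PBS mice gave 4590 genes, T3 in injured wild type 4194, T3 in injured knockouts 85, the knockout on PBS and CCl4 3, T3 by genotype on CCl4 2287 and CCl4 by genotype 0. Falls within 1.5 times were to 3449 for CCl4 in knockout PBS mice and 2903 for T3 by CCl4. The other 8 counts rose, among them CCl4 in wild-type T3 mice to 784, T3 in uninjured wild type to 6173, the knockout on T3 and CCl4 to 4629 and on PBS and oil to 117, and T3 by genotype on oil to 2675. The shares were 32.2% in wild type and 0.0654% in knockouts. Every count that fell with only the compared groups came from a comparison with a PBS CCl4 group, and none that rose did. Those groups varied most on the first principal component (SD 37.2 in wild type and 29.5 in knockouts, against 4.15 to 14.3 in the others). The shared estimate of the spread may thus call too many genes there and too few elsewhere. This link was not tested, nor was the cause of the other changes.

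Leaving out 1 library at a time moved T3 in injured knockouts between 165 (without knockout T3 CCl4 replicate 4) and 591 (without knockout PBS CCl4 replicate 3), with 176 without knockout T3 CCl4 replicate 2, 189 without knockout PBS CCl4 replicate 1 and 237 without replicate 4. The knockout on PBS and CCl4 ran from 70 (without wild-type PBS CCl4 replicate 2) to 1748 (without replicate 4), with 147 without wild-type PBS CCl4 replicate 1, and 120, 964 and 88 without knockout PBS CCl4 replicates 2, 3 and 4. CCl4 by genotype ran from 0 to 14, the latter without wild-type PBS CCl4 replicate 4, and was 1 without wild-type PBS CCl4 replicate 3 or wild-type PBS oil replicate 4. The knockout on PBS and oil ran from 47 (without wild-type PBS oil replicate 2) to 99. CCl4 in wild-type T3 mice ran from 328 (without wild-type T3 oil replicate 4) to 483, with 347 and 345 without wild-type T3 CCl4 replicates 1 and 2, and CCl4 in knockout PBS mice from 2987 (without knockout PBS CCl4 replicate 3) to 4707. The share moved back ran from 35.2% (without wild-type PBS CCl4 replicate 2) to 48.7% (without replicate 4) in wild type. In knockouts it ran from 0.194% (without knockout T3 CCl4 replicate 4) to 0.736%, with 0.208% without knockout T3 CCl4 replicate 2 and 0.361% without knockout PBS CCl4 replicate 1. For all of these the cause was not tested.

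With the replicate number as a block, the counts were 7126 for CCl4 in wild-type PBS mice, 6453 for T3 in injured wild type and 265 for the knockout on PBS and CCl4. The numbers do not pair the mice: libraries of different groups with the same number had a mean correlation of -0.0019 (from -0.348 to 0.510) over 112 pairs, and 4 of 32 libraries were closest to their own number. Sex could not enter the fit, since all mice were female.

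Of the 1096 calls of named genes in all comparisons, 1095 stayed and 1 ended with DESeq2, 1086 and 10 with relative log expression, 1032 and 64 without the filter, 991 and 105 with total counts alone, 1066 and 30 with the block, 1048 and 48 without the 2 farthest libraries, and 969 and 127 with only the compared groups. With 1 library left out at a time 9712 stayed and 944 ended. Of the 214 calls of lists, 16 stayed and 198 ended with the estimated correlation, the alternative that ended most of them. Total counts alone ended 14, the 2 farthest libraries 16. Genes below 0.115 to 0.177 CPM in a library were within the floor of 3 counts, so their absence cannot be told from a low level.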

Other observations

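The tests in this part, and the lists they use, were all chosen after the results were seen, so their outcomes are hypotheses.

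Interferon-induced genes stood among the smallest adjusted p of T3 by CCl4 in wild type and of T3 in uninjured knockouts. A list of other interferon-stimulated genes, without those that prompted it, held 26 tested genes. In uninjured wild-type liver T3 raised all 26 (median log2 of 2.22, list adjusted p = 0.00177 with an estimated correlation), and in uninjured knockouts all 26 as well (median 1.85, 2.80e-04). On CCl4 in wild type the median was 0.00, 8 were higher and 4 lower, and the list was not called (adjusted p = 0.501). On CCl4 in knockouts 6 were higher and none lower (12 adjusted over the list alone, median 0.46, adjusted p = 8.75e-13, and 0.0808 with an estimated correlation). In wild-type PBS mice CCl4 itself raised 20 of the 26 (median 1.04, adjusted p = 4.05e-10, and 0.107 with an estimated correlation). The T3 response was smaller on CCl4 than on oil for 24 of the 26 (median -2.16, 0.00219 with an estimated correlation). The difference between genotypes without injury was smaller (median -0.34, 4 of 26 lower, adjusted p = 0.0210, and 0.589 with an estimated correlation). T3 may thus raise interferon-stimulated genes as a group in uninjured liver with or without Thrb. How it would do so, and in which cells, was not tested.

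The CCl4 comparison called 531 genes in wild-type mice on T3 and 6175 in knockouts on T3. CCl4 is toxic only after activation, mainly by the enzyme of Cyp2e1. On oil T3 lowered Cyp2e1 from 7644 ± 3130 to 1072 ± 193 CPM in wild type (-2.83 ± 0.45) and left it at 4994 ± 720 and 4133 ± 354 CPM in knockouts (-0.27 ± 0.42, adjusted p = 0.711). The difference between genotypes was 2.56 ± 0.60 (adjusted p = 0.00501). Less activation of the last injections in wild-type T3 livers may thus account for part of their smaller injury response, apart from any effect on resolution. After CCl4 the levels were 1063 ± 587 on PBS and 1043 ± 164 on T3 in wild type, so the difference was not there once PBS livers were injured. Enzyme activity and liver damage were not measured in these data.

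Several genes with the widest T3 changes in wild type, such as Mup, Cyp2b and Cyp3a members, are known to differ between male and female liver. A list of other female-biased genes had a median log2 of -0.44 with T3 on oil in wild type, but a mean of 1.14. Its test pointed up (adjusted p = 0.127, and 0.00543 by fry). Male-biased genes had a median of -1.08 (adjusted p = 0.462, and 0.435 by fry). Members went both ways in each, so a shift to the male pattern was left undecided on oil. On CCl4 in wild type T3 raised the female-biased list (8 of 16 higher and none lower, 9 adjusted over the list alone, median 1.48, adjusted p = 1.60e-05, and 0.0424 with an estimated correlation). CCl4 in wild-type PBS mice had lowered both the female-biased (median -1.57, 8 of 16 lower and 2 higher, 9 and 2 alone) and the male-biased list (-1.33, 6 of 12 lower), both at 0.107 with an estimated correlation, so that rise was not separated from a return of genes lost to injury.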
